A study of Homo sapiens with 2 samples.

How the data were processed

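MDA-LM2 cells transfected with a myc-tagged TARBP2 vector were analysed as 1 group of 2 replicates, named from the sample titles. Nothing in the labels says whether the replicates came from separate cultures. Per the labels' protocols, cells were UV cross-linked 48 hours after transfection and prepared by a published HITS-CLIP procedure, with an anti-myc antibody. Reads were aligned with Bowtie to hg19, per the submitters' processing notes. The aligner version, the region caller, its filters and the treatment of reads with several alignments are not given in the sources used here. Whether a region had to be present in both replicates is likewise not given. These steps decide which regions were listed, how long they are and whether copies of a repeat share reads.

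The deposited score was 1 for each region and carries no height. The authors deposited region coordinates as 0-based starts, which are printed here 1-based. The list has no column per replicate, so no replicate was compared with the other, no depth per sample can be given, and no pairing or leave-one-out analysis was made. Names of the deposited regions hold numbers that rise along each chromosome and strand with gaps. What set apart the numbers not among the regions analysed here is not given in the sources used here.

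The last region lay beyond the last annotated gene end of GRCh38 on 14 chromosomes, and coordinates were not converted between builds. The annotation used here, GENCODE 29, is on GRCh38. It served only for gene numbers and gene strand per chromosome, for the spacing of tandem gene families on chromosome 1 and for the exon layout of TARBP2. Assignment of regions to genes, exons and introns, strand relative to genes, gene lists, score by class, GC content, folding, 6-mers and repeats had been planned. They were not run, since a genome and annotation of hg19 were not used here.

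Regions on chromosomes 1 to 22 and X entered the comparisons. Strands were compared with a two-sided exact sign test over 23 chromosomes, and shares were given 95% exact Clopper-Pearson intervals, except that the limit for a count of 0 was 3 counts of the total. Spacing was compared with 1000 random placements on the same chromosome and strand, in place of the planned placement within genes. Numbers in the names were compared with 1000 random draws, and the strands of neighbours with 1000 permutations within chromosomes. Overlap between strands was compared with 100 placements. Correlations used 100000 resamples. Domains joined same-strand regions separated by at most 10 kb. Domains of at least 20 regions were scanned for repeated spacing at lags of 1500 to 8000 nt, with 200 shuffles each. A shorter lag at a whole fraction of the best one was taken as the period where it kept 85% of the correlation. Layouts of domains of at least 8 regions were compared as covered bins of 20 nt by cross-correlation over at least 20 kb, with reversed layouts as the background. A search for neighbouring regions with equal lengths and gap was tried first and was replaced by this one. A tandem gene family was a set of at least 6 genes of 1 name stem whose spacing stayed within 2%. The TARBP2 exon layout was scanned over the regions in bins of 10 nt.

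The planned rule for named genes took the 10 genes with the most regions and the 10 with the most exonic regions per kb. It also took genes of the highest scores, members of gene lists, and APP and ZNF395, none of which were analysed here. Its first parts were applied to domains instead: the 10 with the most regions and the 10 with the most regions per kb among those of at least 10 regions. Longest regions were given for the first 3. This change, the domains, the period lags, the layout settings and the exon padding were chosen after the regions had been examined. Regions named for their length, for overlap between strands or for a repeated layout were singled out after their values were seen. The alternatives tried were other sets of regions, joining distances, placement blocks, neighbour distances, gene sets, lags, overlaps and exon paddings.

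The statistics were tested on simulated data, of 4000 regions for spacing, strand and numbers and of fewer regions for arrays and layouts. In sets of uniformly placed regions the mean fold over random placement was 1.00, and 30 of 500 sets had p under 0.05. The same-strand share of simulated pairs was 98.2%, the period of simulated arrays was recovered within 2% in 92% of them, and 3 of 3 copied layouts were found. The copied layouts were compared over at least 10 kb in place of 20 kb, with small shifts of region starts and no missing regions. Their recovery therefore does not test the setting used for the regions. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.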

Results

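RNA bound by TARBP2 was mapped in MDA-LM2 cells, a human breast cancer line selected for spread to the lung. TARBP2 is a double-stranded RNA-binding protein and a partner of the nuclease Dicer in microRNA processing. The cells were transfected with a myc-tagged TARBP2 vector, and 48 hours later they were UV cross-linked and taken through HITS-CLIP, in which RNA cross-linked to a protein is co-purified with it and sequenced. The study held 1 group of 2 replicates. The processed data were 1 list of stranded regions on hg19 for the whole group, so values are given without a replicate error. Each region carried a score of 1, so the depth behind a region is unknown. No comparison between groups or with a control library was made. The question addressed is where in the genome the TARBP2-bound regions lay. Regions were not assigned to genes, because no gene annotation of hg19 was used here. The p-values below come from sign tests or correlations over chromosomes, or from comparison with random placements, draws, permutations or shuffles. None of them measures variation between cultures. The comparison of spacing was planned before the data were examined, with placement within genes in place of placement on chromosomes. The other comparisons were chosen after the regions had been examined.

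The regions analysed here, which may not be all those called, numbered 23412, of which 23408 lay on chromosomes 1 to 22 and X and 4 on the mitochondrial genome. Together they covered 8.18 Mb. Region length ranged from 101 to 9742 nt, with a median of 253 nt and quartiles of 248 and 374 nt. The 90th percentile was 575 nt, and 523 regions (2.23%) were longer than 1000 nt. One length stood apart: 4623 regions (19.7%, 95% exact binomial interval 19.2 to 20.3%) were 249 nt long, against 334 regions at the next most common length of 247 nt. The region names held numbers up to 155642 that rose along each chromosome and strand. The regions analysed here made up 14.9 to 15.2% (95% exact binomial interval) of these numbers. All intervals cover counting error only.

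Of the 15 longest regions, 8 lay on chromosome 7 and 3 on chromosome 16. The 3 on chromosome 16 lay in 3 of the 5 stretches with similar layouts described below, so they may not be separate cases. The longest, of 9742 nt, lay on the minus strand at chromosome 7 from 102182792 to 102192533. Regions of 7972 nt (102282505 to 102290476) and 7265 nt (102270689 to 102277953) lay on the same strand nearby. The longest region on the plus strand was 5895 nt, at chromosome 1 from 564555 to 570449. The mitochondrial regions all lay on the plus strand, at 1870 to 2503, 2766 to 2966, 12515 to 12741 and 13267 to 13480.

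Chromosomes with more genes tended to hold more regions, though chromosome length was not considered. Chromosome 1 held 2259 regions, chromosome 3 held 1685 and chromosome 7 held 1629, while chromosome 21 held 206. Over the 23 chromosomes, the number of regions correlated with the number of protein-coding genes in GENCODE 29 (Pearson r = 0.834, Spearman rho = 0.809). Each permutation p was 1e-05, the smallest that 100000 resamples can give. Without chromosomes 1 and 19, the farthest from the median gene number, r was 0.837. This was 1 of 3 relations computed, and the Benjamini-Hochberg adjusted p was 1e-05 for r and 1.5e-05 for rho. Chromosome 7 had the most regions per 100 protein-coding genes (179), followed by chromosomes 3 (157) and 5 (154), against a median of 120. Chromosomes 19 (64.1) and 17 (80.8) had the fewest. When regions on the same strand within 10 kb were counted once, chromosome 18 ranked highest with 128 per 100 genes, chromosome 7 ranked 9 and chromosome 19 remained lowest with 34.0.

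More regions lay on the minus strand of the genome than on the plus strand. On chromosomes 1 to 22 and X, 14251 regions were on the minus strand and 9157 on the plus strand, a minus share of 60.9% (60.3 to 61.5%). The minus strand held more on 23 of 23 chromosomes (two-sided exact sign test, p = 2.38e-07). The share per chromosome averaged 61.1% ± 4.45 (SD over chromosomes). It ranged from 51.8% on chromosome 9 to 68.6% on chromosome 22. Of the 19864 protein-coding genes of GENCODE 29 on these chromosomes, 49.6% are on the minus strand. Of the 155021 numbers from the first to the last listed on each chromosome and strand, 57.2% fell on the minus strand.

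**Figure D1:**
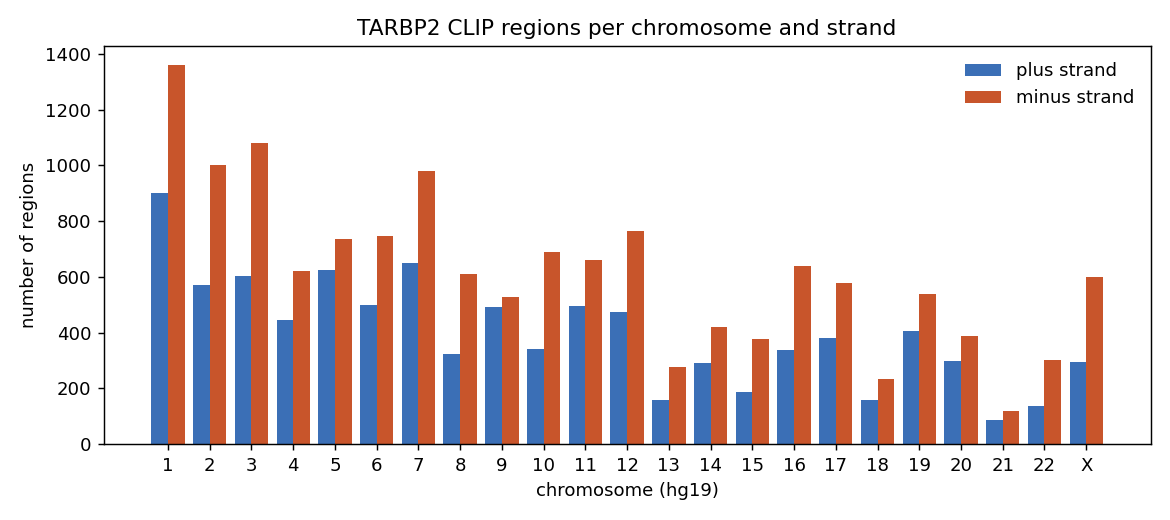
Number of TARBP2 CLIP regions (vertical axis) on the plus strand (blue) and minus strand (orange) of each chromosome (horizontal axis, hg19). The minus bar is the higher on 23 of 23 chromosomes, with 899 plus and 1360 minus regions on chromosome 1 and 493 plus and 529 minus regions on chromosome 9.

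The exact length of 249 nt was more common on the minus strand. It was the length of 3871 minus-strand regions (27.2%, 26.4 to 27.9%) and 752 plus-strand regions (8.21%, 7.66 to 8.79%). The difference averaged 19.2 percentage points ± 4.14 (SD over chromosomes) and had the same direction on 23 of 23 chromosomes (exact sign test, p = 2.38e-07). Lengths close to 249 nt were not. The 10 nt bin from 240 nt held 1111 plus-strand and 731 minus-strand regions of other lengths, and the bin from 250 nt 1011 and 962. Both strands thus had a peak near 249 nt, more often of exactly this length on the minus strand. Without regions of exactly 249 nt the minus share fell to 55.3% (54.5 to 56.0%), and the minus strand held more on 20 of 23 chromosomes (exact sign test, p = 0.000488). This cut removes more of the minus-strand peak than of the plus-strand peak, so the shares without 249 nt do not measure the part of the peak. Regions of other lengths that had no same-strand neighbour within 10 kb were 52.4% minus (51.4 to 53.4%, exact sign test, p = 0.0347). Regions of other lengths with such a neighbour were 58.2% minus (57.2 to 59.2%, exact sign test, p = 0.00434).

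**Figure D2:**
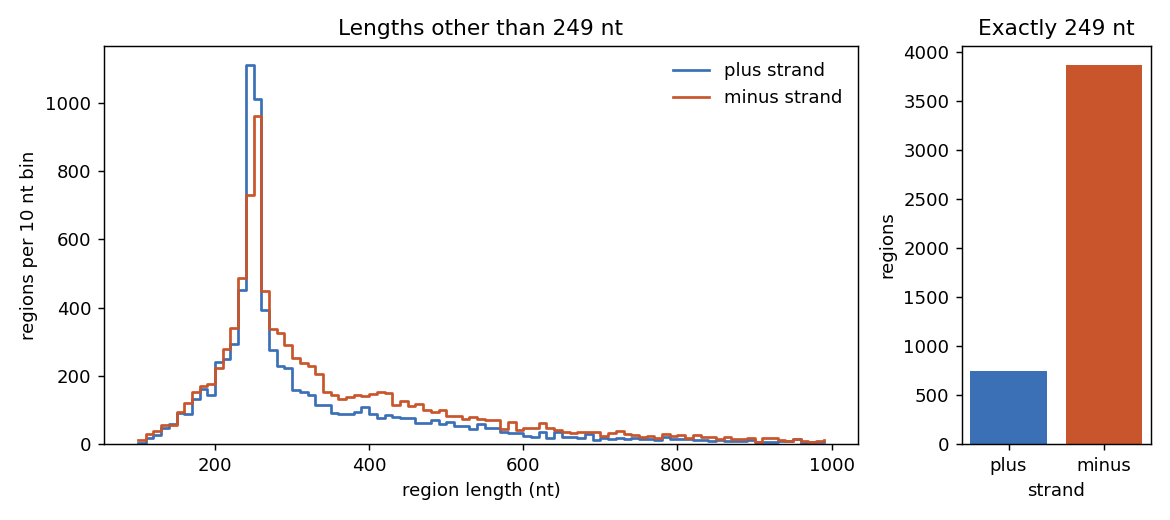
Left, number of regions per 10 nt bin of region length for lengths other than 249 nt, on the plus strand (blue) and minus strand (orange) of chromosomes 1 to 22 and X. Right, number of regions of exactly 249 nt, 752 on the plus strand and 3871 on the minus strand.

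Regions lay close together on the same strand. A same-strand neighbour within 1000 nt was found for 4592 regions (19.6%), against 1.21% ± 0.105 (SD over 1000 placements) when regions were placed at random on their own chromosome and strand. This was a 16.2-fold difference (two-sided permutation p = 0.000999, the smallest that 1000 placements can give). When each region was placed within its own 1 Mb block the difference was 5.19-fold, and among regions at or above the median length it was 38.7-fold. Within 10 kb, 44.8% of regions had a same-strand neighbour, against 8.85% at random placement (5.06-fold). No region had one within 100 nt, and the smallest gap was 101 nt. The region names begin with the word merge, so joining of closer regions before deposit may have set this limit. The 0.411% at random placement is therefore no measure of spacing at this distance. Of 8627 neighbouring pairs within 10 kb, taken over both strands, 85.1% (84.3 to 85.9%) lay on the same strand, against 52.5% ± 0.536 when strands were permuted (permutation p = 0.000999). Neither the placements nor the permuted strands kept regions within genes. These differences therefore cannot tell clustered binding from transcription that is confined to part of the genome and to 1 strand. Successive numbers in the names were also more frequent than in random draws, with 5290 pairs against 3735 ± 50.3 (SD over 1000 draws), a 1.42-fold difference (permutation p = 0.000999).

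Same-strand regions separated by at most 10 kb were joined into 15826 domains, and 12929 of these (81.7%) held 1 region. The 135 domains of at least 10 regions held 2059 regions (8.80%) and had a median span of 31.8 kb. At a joining distance of 5 kb there were 87 such domains and at 20 kb 215. Regions in the 135 domains were longer, with a median of 451 nt against 250 nt elsewhere. This held on each of the 19 chromosomes that had such domains (exact sign test, p = 3.81e-06).

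The domain with the most regions was on the minus strand of chromosome X from 114954714 to 115018401, with 46 regions over 63.7 kb. Its longest region was 1462 nt (114999661 to 115001122). The next was on the minus strand of chromosome 1 from 1724275 to 1828432, with 45 regions and a longest region of 3548 nt (1811183 to 1814730). A minus-strand domain on chromosome 20 from 30252674 to 30303308 held 34 regions that covered 58.4% of it, the longest being 3014 nt (30289743 to 30292756). Chromosome 1 also had a pair of domains on opposite strands of the same stretch. The plus-strand domain from 228743533 to 228782206 held 33 regions, and the minus-strand domain from 228742455 to 228782155 held 32. The other domains among the 10 with the most regions held 25 to 30 regions each. They lay on chromosome 12 (57739222 to 57823712), chromosome 11 (122541491 to 122609559), chromosome 7 (75062462 to 75139778), chromosome 10 (101680317 to 101761461) and chromosome 3 (48078643 to 48136348). Among domains of at least 10 regions, the most regions per kb (0.932) were found on the plus strand of chromosome 1 from 151047346 to 151058078. Its longest region was 984 nt (151052051 to 151053034).

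Few regions overlapped a region on the other strand. Of the plus-strand regions, 148 (1.62%, 1.37 to 1.90%) overlapped a minus-strand region by at least 1 nt, against a mean of 33.0 and a maximum of 48 in 100 random placements (permutation p = 0.0099, the smallest that 100 placements can give). The paired domains of chromosome 1 near 228743533 supplied 27 of them. Another 4 were the whole of a plus-strand domain on chromosome 5 (134259477 to 134263692), and 3 of the 6 regions of a plus-strand domain on chromosome 12 (53895194 to 53900148) overlapped a minus-strand region.

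Repeated spacing was found in 4 of the 23 domains of at least 20 regions. In each, the autocorrelation of covered positions exceeded that of all 200 shuffles of its regions and gaps (permutation p = 0.00498, the smallest that 200 shuffles can give, Benjamini-Hochberg adjusted p = 0.0286). The domain on chromosome X repeated at 2981 nt (r = 0.433, highest shuffled 0.261). The plus-strand domain of chromosome 1 near 228743533 repeated at 2239 nt (r = 0.588), a whole fraction of its best lag of 6710 nt (r = 0.618, highest shuffled 0.425). The minus-strand domain opposite repeated at 2238 nt (r = 0.329), and its best lag exceeded the shuffles by less (r = 0.334 against 0.316). The domain of chromosome 1 from 1724275 had its best lag at 2077 nt (r = 0.268, highest shuffled 0.226), and by the same rule a period of 1018 nt (r = 0.253), which is shorter than the lags scanned. It did not exceed the shuffles when lags from 500 nt were allowed (permutation test, adjusted p = 0.866). The array on chromosome 1 had 33 plus-strand regions covering 56.4% of its 39.8 kb and 32 minus-strand regions covering 48.5%. The array on chromosome X had 0 plus-strand regions among 46, which allows a share of up to 6.52% (3 counts of the total).

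**Figure D3:**
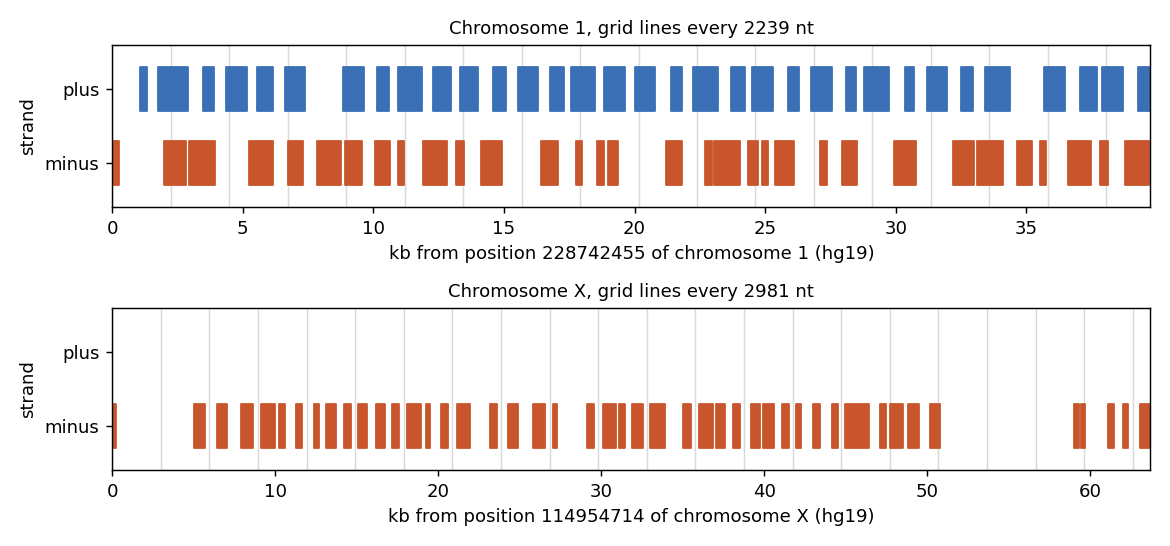
Regions on the plus strand (blue) and minus strand (orange) of the arrays on chromosome 1 (top) and chromosome X (bottom), against position in kb from the start of each array (hg19). Grid lines are drawn every 2239 nt and 2981 nt. Chromosome 1 has 33 plus and 32 minus regions, and chromosome X has 46 minus regions.

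On chromosome 16, 5 domains of 12 to 16 regions had similar layouts. They lay at 21426639 to 21457102, 21856405 to 21889597, 29507136 to 29537577 and 30247089 to 30277684 on the minus strand, and at 22504625 to 22534969 on the plus strand. With layouts compared in the direction of the strand over at least 20 kb, their 10 pairs were the 10 highest of 13861 (r = 0.716 to 0.832), ahead of 0.683 for the next pair. The highest value of a reversed layout was 0.719, and 9 of the 10 pairs exceeded it. The overlap of 20 kb was chosen after results at 10 and 15 kb had been seen. At 15 kb, 7 pairs exceeded the highest reversed layout, 6 of them on chromosome 16, and at 10 kb 0 did. The range of r of these pairs was the same at each overlap, while the highest reversed layout was 0.983 at 10 kb, 0.666 at 25 kb and 0.538 at 30 kb. At 25 kb the 10 pairs and no pair of other domains exceeded it. At 30 kb, chosen last and close to the overlap of these pairs, the 10 pairs and 4 pairs of other domains exceeded it.

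**Figure D4:**
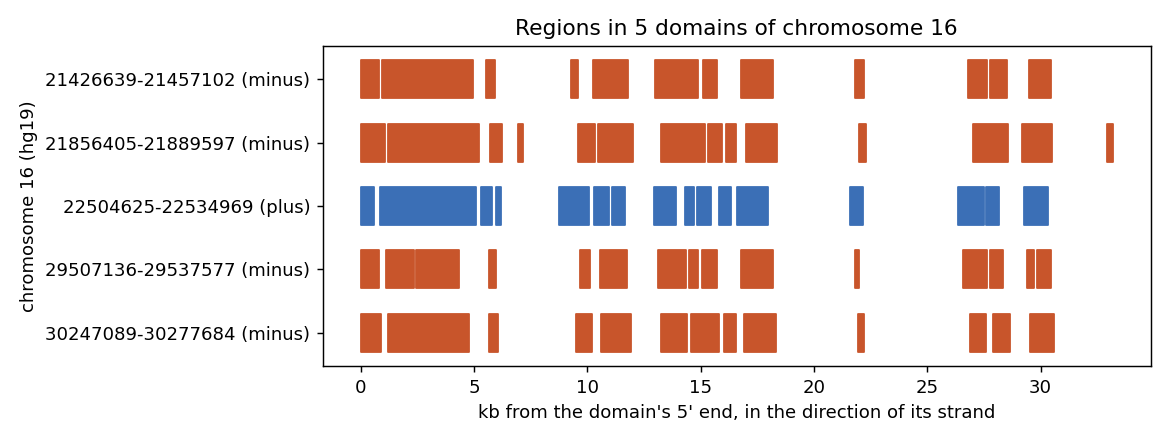
Regions in 5 domains of chromosome 16 (hg19), each drawn in kb from its 5′ end in the direction of its strand (plus in blue, minus in orange). The layouts of the 10 pairs correlated at r = 0.716 to 0.832.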

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

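The alternatives for spacing in regions at or above the median length, for joining close regions and for the number of regions were planned, and the other tests here were chosen after the result was seen. Of 36 alternative settings, 30 kept the direction and the side of the threshold, or a count within 1.5 times. Joining regions within 50 nt and leaving out regions under 20 nt changed nothing, since no region met either condition. The minus share was 55.3 to 60.9% in these settings, and lower (52.4%) in regions other than 249 nt that were alone in their domain. The 249 nt difference was 9.42 to 26.6 percentage points, and the spacing within 1000 nt 5.19-fold to 38.7-fold. The number of domains of at least 10 regions moved from 135 to 87 at a joining distance of 5 kb and to 215 at 20 kb, by construction of the joining. Pairs with the same layout fell from 9 to 0 when an overlap of 10 kb was allowed, where the highest reversed layout rose to 0.983, and rose to 14 at 30 kb, where it was 0.538. The scan for the TARBP2 exon layout picked other chromosomes without padding (r = 0.685) and with 50 nt (r = 0.617), and the cause was not tested. No paired analysis was possible because there is 1 group and the regions carry no replicate. Leaving out a replicate was not possible for the same reason. Alternatives for annotation, strand relative to genes, GC content, folding, stems, 6-mers, repeats, genes, gene lists, score and position, and placement within genes, were not run. Depth is unknown, so it could not be used to weigh regions.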

Other observations

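In this part the test of gene strand was fixed before its result was seen, and the other tests were chosen after. No biological explanation that rests on a comparison of groups was tested, since the design holds 1 group.

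The minus-strand excess (60.9% of regions) was weighed against 3 explanations. Regions of exactly 249 nt were 83.7% minus. Without them the share was still 55.3% (exact sign test over chromosomes, p = 0.000488), so by count they are not the whole excess. Their part cannot be read from this fall or from the shares of other lengths below. The cut removes 27.2% of minus-strand and 8.21% of plus-strand regions, while other lengths in the bin from 240 nt were more common on the plus strand (1111 against 731). Stretches of 249 nt joined into longer regions, if any, would remain, so their full part could not be tested. Regions of other lengths were 52.4% minus without a same-strand neighbour within 10 kb and 58.2% minus with one. Gene content was argued against, since the minus strand holds 48.6% of protein-coding gene span in GENCODE 29. Dense domains by themselves are also not the whole excess, as the share with 1 count per domain was 60.9%. That count keeps the regions of 249 nt, so it does not weigh the 2 explanations together. By domain size the minus share was 59.6 to 61.0% up to 19 regions. It was 75.9% (72.4 to 79.3%) in domains of at least 20 regions, which held 2.63% of regions. A step of region calling or filtering that treated the strands differently may be involved. Of minus-strand numbers in the names 16.1% were listed, against 13.8% of plus-strand numbers (higher on 21 of 23 chromosomes, exact sign test, p = 6.6e-05). These shares bear only on listing, since 57.2% of all numbers already fell on the minus strand. A calling or filtering step stays open because the caller is not given in the sources used here.

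In the repeated layouts of chromosome 1, the period of 2239 nt differed by -0.0892% from the 2241 nt spacing (SD 8.71) of the 17 tandem 5S ribosomal RNA genes, the only chromosome 1 family with regular spacing, so a 5S array is a candidate source. One-strand reads of 5S ribosomal RNA do not account for the whole signal, since the strand with fewer regions held 49.2% of them. DNA of repeat arrays in general would give both strands in each array, but the array on chromosome X had 0% on the other strand. That speaks only against DNA as a source in every array, and whether DNA gave the regions on both strands of chromosome 1 was not tested. On chromosome 16, copies of 1 duplicated segment are a candidate explanation, and of the 10 pairs 9 exceeded the highest reversed layout over at least 20 kb, 10 at 25 kb (with no pair of other domains) and 10 at 30 kb (with 4 pairs of other domains). These values point away from chance likeness, but 6 pairs exceeded it at 15 kb and 0 at 10 kb, where short overlaps raised the reversed values, and the longer overlaps were chosen after these, so both stay open.

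The transfected gene is itself a possible source of regions. The chromosome 12 location was looked at because it was known beforehand as the TARBP2 locus, and the 100 nt padding of exons was chosen after the unpadded scan had picked chromosome 17 (r = 0.685). With that padding the layout of the 9 exons of TARBP2-201 fitted best on the plus strand of chromosome 12 from 53894821 (r = 0.715, next location 0.613, highest reversed 0.572). There 6 plus-strand regions overlapped 9 of 9 exons and 3 minus-strand regions (33.3%) overlapped 2, and a padding of 150 nt picked the same location (r = 0.678, next 0.581, highest reversed 0.588), but it gave r = 0.461 with 50 nt and 0.219 without padding, where other chromosomes were picked. The scan alone cannot tell TARBP2 exon sequence from a chance match of layouts, as only 2 of 4 paddings picked this location. If the locus known beforehand is taken as given, these regions lie at TARBP2 whatever the scan picks. That locus was not checked here, since no hg19 annotation was used, and vector sequence was not tested.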
